A study of Homo sapiens with 20 samples.

How the data were processed

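RNA of NCI-H522 cells, a human non-small-cell lung cancer line, was hybridised to 20 two-colour Agilent arrays. On each array the RNA of a treated culture carried Cy3 and the RNA of untreated H522 cells, the common reference, carried Cy5, per the labels, so no dye was swapped. The treatments were an adenovirus carrying GFP-BRG1, an adenovirus carrying GFP alone (both at a multiplicity of infection of 20), 100 nM trichostatin A (TSA, an inhibitor of histone deacetylases), 5 uM 5-aza-2'-deoxycytidine (5dAzaC, an inhibitor of DNA methyltransferases) and DMSO. The labels give 48 h for the drugs and do not name the vehicle of 5dAzaC. Each treatment had 1 culture and 4 technical arrays, so every p-value measures the error between arrays of 1 RNA sample and not the spread between cultures. The 4 arrays of each treatment lay on a slide of their own, so slide and treatment cannot be told apart and no slide block could be fitted.

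The authors scanned the arrays and quantified the spots with Agilent Feature Extraction 9.1.3.1. The deposited scanner files give the mean signal, the median local background and the processed signal of each spot as intensity in scanner units. Per the file headers, the processed signal had already been background-subtracted and dye-normalised. The deposited files also hold a log10 ratio of the red over the green processed signal per spot, and the other deposited columns read are 0 or 1 marks per spot for saturation, uneven spots and signal well above background. The authors' series table holds a log2 ratio of treated over reference per spot, with array medians between -0.0058 and 0.0114. Its normalisation is not stated, beyond limma being named in the submitters' processing notes. Across probes it correlated with the log2 ratios computed here at r of 0.988 to 0.999, with slopes of 0.98 to 1.01 (probes are not independent replicates).

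The analysis started from the mean signals of the 45015 spots per array. In limma 3.58.1 (R 4.3.3) they were background-corrected by normexp with an offset of 50 and normalised within arrays by loess, with the 1639 control spots given no weight. Spots marked as uneven or as population outliers were left out, and 36 missing values of detected probes were replaced by the group mean. The log2 ratio was turned to treated over untreated. Of 41000 probes, 36303 were well above background in Cy3 on all 4 arrays of at least 1 group and were kept. Arrays had 29291 to 37522 probes well above background in Cy3, and the number of arrays limits the precision. Gene names came from a RefSeq gene table of assembly GRCh38.p14, used for names alone, since the build behind the array is not given. By accession 23434 probes matched, by symbol 2317 and by an older symbol 1043, and 14206 probes matched nothing and were set apart as unnamed. For each gene the probe with the highest mean intensity over the 20 arrays was used, which left 16543 genes.

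One linear model with a mean per treatment was fitted to all 20 arrays (lmFit and eBayes, 15 residual degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a difference of at least 2-fold, and called genes are those described as higher, lower, risen or fallen. The comparisons were BRG1 against GFP, TSA against DMSO, 5dAzaC against DMSO, the control cultures DMSO against GFP, the differences between the BRG1 effect and each drug effect, and TSA against 5dAzaC. Errors after a plus-minus sign are standard errors of the log2 difference from the model, unless SD is written, and n is the number of arrays per group. The overlap of called genes was set against the number that independent lists would share, and the covariance of TSA and 5dAzaC against 50 simulations of unchanged groups sharing the DMSO arrays, and both against the 6 ways of parting the DMSO arrays between the drugs.

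Altogether 30 gene lists were tested in each treatment comparison with camera, at a preset correlation between genes of 0.01, and adjusted over the 90 tests. The tests were repeated with an estimated correlation and with fry. The comparisons, lists, tests, named-gene rule and most alternatives were fixed before the data were examined. The rule named SMARCA4 and SMARCA2, the 8 higher and 8 lower genes with the largest differences per treatment comparison whose arrays did not overlap, up to 4 called members of each list described with members the list is known for, up to 8 genes called alike in all 3 comparisons, and 4 genes per test of a difference. Uninformative symbols, Y-linked genes and XIST were left out, and some genes that the rule names are not reported here. DDIT3, HSPA5, HSP90B1 and PDIA4 in the 5dAzaC stress list, ASNS, PSAT1 and GBP1 in the BRG1 lists, ISG15 in the 5dAzaC interferon list, and the genes named for DMSO against GFP and for BRG1 against DMSO lie outside the rule and were chosen after their values were seen.

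On data simulated from the array spread of 16543 genes, a log2 difference of 1.2 was called for 100% of genes for BRG1 against GFP, 100% for TSA against DMSO and 96% for 5dAzaC against DMSO. A difference of 0.8, which lies below the fold minimum, was called for 2%, 2% and 0% of genes in the same order. No unchanged gene of the 16343 was called in any of these comparisons. In the TSA simulation camera found 2 of 2 shifted lists and called 0 of the others. Genes varied independently there, so it does not test false list calls among correlated genes. The planted shifts were also larger than the median of any list called for TSA. The alternatives tried were no background correction, the Agilent processed signals, median centring, Aquantile scaling between arrays, the Cy3 channel alone, the authors' table, other filters, fold minimums and probe rules, other control groups, a replicate block, averaged arrays and leaving out each array. Leaving out the probes that hold the sequence CCTCCC, and counting BRG1 calls made against both control cultures, were added after seeing the data. Unnamed probes entered only the alternative that tested every probe and 1 separate count.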

Results

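Gene expression was measured in 5 cultures of NCI-H522 cells, a non-small-cell lung cancer line, each hybridised to 4 arrays against untreated H522 RNA. One culture received an adenovirus carrying GFP-BRG1, where BRG1 is the ATPase of the SWI/SNF chromatin remodelling complex encoded by SMARCA4, and its control received an adenovirus carrying GFP. The other cultures received TSA, 5dAzaC or DMSO. Between 71.4% and 91.5% of the 41000 probes were well above background in the treated channel, the lowest share being on the second 5dAzaC array. Within groups the lowest correlation across genes between arrays was 0.957 for GFP, 0.957 for BRG1, 0.554 for DMSO, 0.817 for TSA and 0.876 for 5dAzaC. The median SD of a gene's log2 ratio within a group lay between 0.083 and 0.106. Against the untreated reference, 1773 of 16543 genes were called in BRG1, 1573 in GFP, 708 in 5dAzaC, 64 in TSA and 3 in DMSO (limma).

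The comparison of BRG1 with GFP asks which genes respond when BRG1 is put back into these cells. A pair of SMARCA4 probes rose in the BRG1 culture. Probe A_23_P39040 stood 177-fold above GFP (log2 difference 7.47 ± 0.21, n = 4) and probe A_24_P212851 43.5-fold above it (5.44 ± 0.12, and 5.06 with median centring). In the Cy3 channel alone, which leaves out the reference channel, the differences were 8.63 and 10.76, so their size depends on the processing. The third probe, A_23_P39034, which was the brightest over all arrays and stood for the gene in the model, differed by 0.41 ± 0.06 (0.87 with median centring), and by -0.39 from DMSO. In GFP, DMSO, TSA and 5dAzaC the mean log2 ratio of A_23_P39040 to untreated cells was 0.05, 0.18, 0.09 and 0.03, with SDs of 0.46, 0.17, 0.30 and 0.31 (n = 4). Neither probe of SMARCA2, which encodes the related ATPase BRM, was well above background in any group as a whole, and 1 DMSO array passed for 1 of them.

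**Figure D1:**
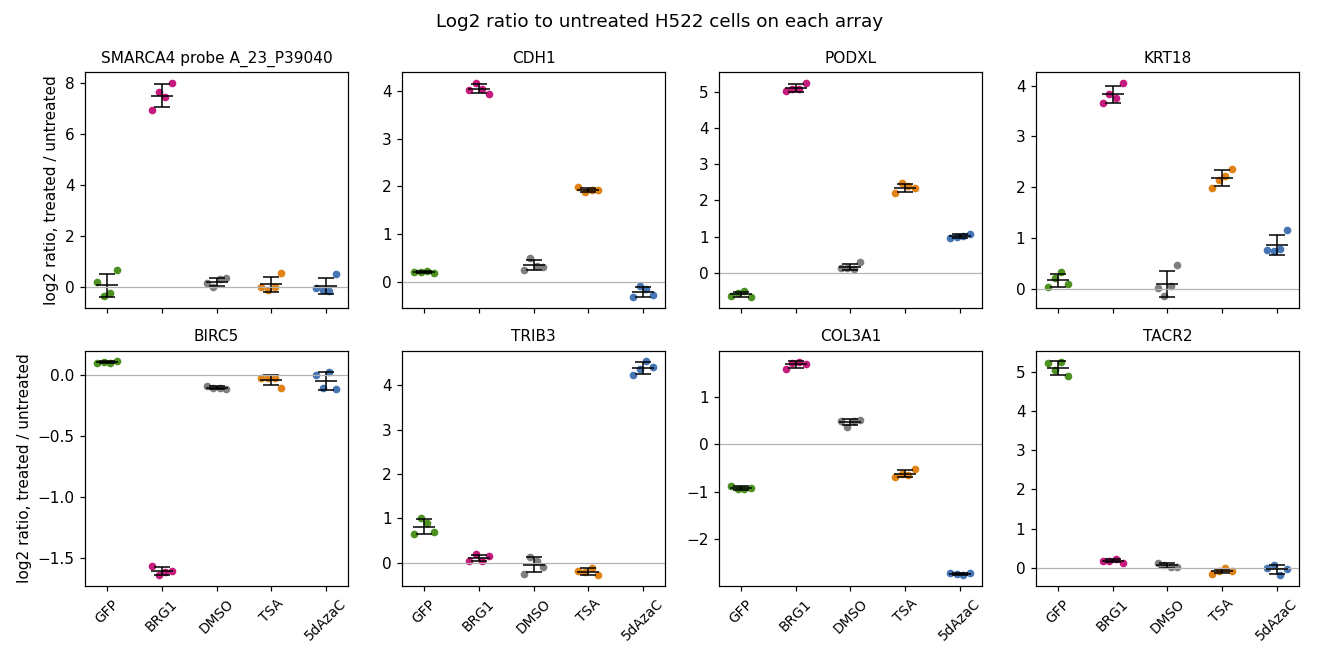
Log2 ratio of treated over untreated H522 cells on each array (points, 4 per culture), with the mean and SD of each culture (bars), for a SMARCA4 probe and 7 genes. The SMARCA4 probe averaged 7.52 in BRG1 and 0.05 in GFP, PODXL 5.10 in BRG1 and 2.35 in TSA, TRIB3 4.39 in 5dAzaC, and TACR2, on a probe with CCTCCC, 5.10 in GFP alone among the 5 cultures.

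In BRG1 against GFP, 2679 of 16543 genes were called, 1856 higher and 823 lower. The largest rises were those of PODXL, which encodes the cell-surface sialomucin podocalyxin (52.0-fold, 5.70 ± 0.07, n = 4, adjusted p = 2.98e-25), GPNMB, a membrane glycoprotein (43.4-fold, 5.44 ± 0.10), and the adhesion receptor gene ADGRG1 (40.8-fold, 5.35 ± 0.09). HAS1, a hyaluronan synthase, rose 35.1-fold, TMEM125 33.3-fold, the myosin gene MYH13 30.9-fold (its probe was well above background on 2 of 4 GFP arrays), the aldo-keto reductase AKR1C1 21.2-fold and SELENBP1 20.2-fold. All 8 were also called higher in BRG1 against DMSO. Among the largest falls were those of the tachykinin receptor gene TACR2 (-4.92 ± 0.07), TCL6 (-3.98 ± 0.08), ACBD4 (-3.80 ± 0.07), PFKFB3 (-3.64 ± 0.30), COL10A1 (-3.42 ± 0.08), FYB1 (-3.31 ± 0.12) and THEM5 (-3.30 ± 0.06). Of these 7, PFKFB3 alone was also called lower against DMSO. The others had mean log2 ratios to untreated cells of 3.71 to 5.10 in GFP and of 0.66 or less in BRG1, so these differences came from high values on the GFP arrays. The probes of TACR2 and THEM5 hold the sequence CCTCCC, which went with high signal on the GFP arrays. With the mean of all probes per gene TCL6 (-0.85) and PFKFB3 (-0.51) were no longer called. Other detected probes of these genes did not follow: those of TCL6 stood between -0.04 and 0.06 in GFP, the other probe of ACBD4 differed by 0.78 between BRG1 and GFP, and the other 3 of PFKFB3 by 0.86, 0.28 and 0.45.

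**Figure D2:**
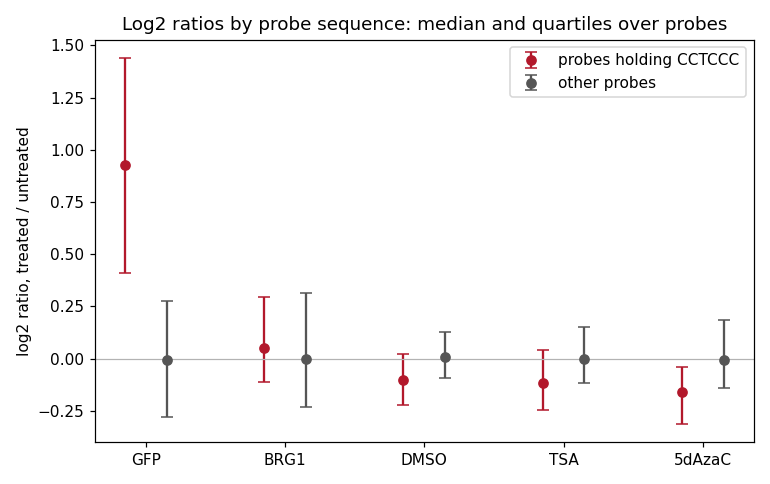
Log2 ratio of treated over untreated cells for the 515 detected probes holding CCTCCC and the 35788 others in each culture; points are medians over probes and bars run between the quartiles. In GFP the median was 0.93 with CCTCCC and -0.01 without it.

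Epithelial genes rose in BRG1. Of 29 measured, 13 were higher, 0 lower and 16 not called against GFP, with 13 higher when adjusted over the list alone. CDH1, which encodes E-cadherin, rose 14.4-fold (3.85 ± 0.06), the keratin genes KRT18 and KRT19 rose 12.7-fold and 8.80-fold, and CDH3, which encodes P-cadherin, 8.69-fold. EPCAM was not called (0.76 ± 0.11), except with median centring (1.04). The list as a whole was shifted upward (camera adjusted p = 0.00394). Adhesion and matrix remodelling genes rose as well, 17 of 38 being higher and 0 lower, also adjusted over the list alone (adjusted p = 2.3e-05). Among them were the integrin gene ITGA3 (14.3-fold), the urokinase gene PLAU (13.8-fold), the laminin gene LAMB1 (13.8-fold) and the plasminogen activator gene PLAT (12.8-fold). Mesenchymal genes moved in the same direction as the epithelial ones, with 12 of 30 higher, 0 lower and 12 higher when adjusted over the list alone (adjusted p = 0.00934). PDGFRB, whose probe was well above background on 2 of 4 GFP arrays, rose 14.6-fold, SPARC by 3.17 on the log2 scale, and the collagen genes COL5A1 and COL1A1 6.61-fold and 6.22-fold, while VIM was not called (0.64 ± 0.09). Of the 15 genes reported as responsive to BRG1 or BRM in other deficient lines, 7 were higher and 1 lower, over all genes and adjusted over the list alone (adjusted p = 0.0021). CRYAB rose by 4.09 on the log2 scale and CD44, the hyaluronan receptor gene, 7.43-fold, and GBP1 was the member that fell (-2.44 ± 0.07), from 2.28 above untreated cells in GFP.

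Heat shock genes rose in BRG1, with 9 of 16 higher and 0 lower against GFP, also adjusted over the list alone (adjusted p = 0.00013). SERPINH1 rose 9.15-fold, DNAJB1 8.41-fold and HSPA1A 6.43-fold. The median log2 ratio of the list to untreated cells was 1.80 in BRG1, 0.53 in GFP and -0.02 in DMSO. Of 25 cholesterol synthesis genes, 12 were higher and 1 lower in BRG1 against GFP, also adjusted over the list alone (adjusted p = 0.000249). TM7SF2, which encodes a sterol reductase, rose 5.79-fold, and STARD4, which encodes a sterol carrier, fell (-2.07 ± 0.08). Neither was called in BRG1 against DMSO: TM7SF2 stood below untreated cells in GFP (-1.79), and STARD4 above them in GFP (1.87) and 0.10 above DMSO in BRG1. Against DMSO 5 of the 25 genes were higher and 0 lower. Hypoxia and glycolysis genes were shifted upward (adjusted p = 0.00864), with 3 of 24 higher and 1 lower, also adjusted over the list alone. The glucose transporter gene SLC2A1 rose 7.92-fold and HK2 3.34-fold, and PFKFB3 was the member that fell, on 1 of its 4 probes. All 7 lists described so far, and that of genes responsive to BRG1 or BRM among them, stayed below 0.05 with an estimated correlation (largest adjusted p = 0.0324).

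DNA replication genes fell in BRG1 against GFP. Of 40, 10 were lower, 0 higher and 30 not called, with 10 lower when adjusted over the list alone (adjusted p = 6.65e-07, and 0.00666 with an estimated correlation). Among them CDC45, CHAF1B and RRM2 were each 2.52-fold lower, and these 3 were not called with median centring (-0.98, -0.92 and -0.92), nor was RRM2 with the mean of all probes (-0.90), its other probe differing by -0.47. The median log2 ratio of the list to untreated cells was 0.62 in GFP, -0.09 in BRG1 and 0.04 in DMSO. Against DMSO 2 of the 40 were lower in BRG1 and the list test gave an adjusted p of 0.0903. Of 30 mitosis genes, 2 were lower in BRG1 against GFP, also adjusted over the list alone. They were BIRC5, which encodes survivin (3.29-fold lower, -1.72 ± 0.05), and NUF2, a kinetochore gene (2.54-fold lower), which missed the fold minimum with median centring (-0.88). The mitosis list had an adjusted p of 0.0248, which became an adjusted p of 0.242 with an estimated correlation, and its median difference of -0.14 changed sign to 0.25 with median centring. Both adenovirus cultures had mitosis genes below untreated cells, with list medians of -0.95 in GFP (SD 0.06, n = 4) and -1.17 in BRG1 (SD 0.06), against 0.02 in DMSO. In BRG1 against DMSO 19 of the 30 were lower and 0 higher (adjusted p = 2.64e-17, and 0.00117 with an estimated correlation).

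**Figure D3:**
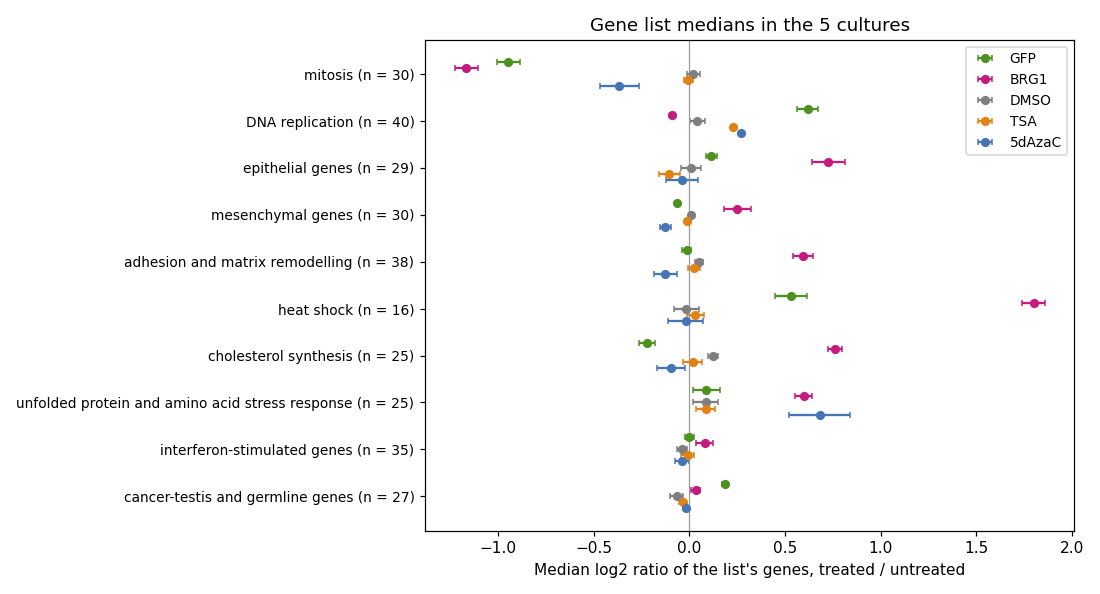
Median log2 ratio of treated over untreated cells for the measured genes of 10 lists (n, number of genes), in each of the 5 cultures; points are medians over genes of the 4-array mean, and bars the SD of the list median over the 4 arrays. Mitosis genes stood at -0.95 in GFP and -1.17 in BRG1, and heat shock genes at 1.80 in BRG1.

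Further lists were called for BRG1 against GFP at the preset correlation and not with the estimated one. Of 25 genes of the unfolded protein and amino acid stress response, 13 were higher and 2 lower, also adjusted over the list alone (adjusted p = 0.0245, and adjusted p = 0.0838 with an estimated correlation). ATF3, a stress-induced transcription factor gene, rose 7.90-fold, DDIT4 5.76-fold and VLDLR 4.55-fold, while ASNS (-1.23 ± 0.08) and PSAT1 (-1.09 ± 0.09), which encode enzymes of amino acid synthesis, fell. With median centring ASNS (-0.95) and PSAT1 (-0.64) missed the fold minimum, as did ASNS with the mean of all probes (-0.73, its other probe differing by -0.23) and PSAT1 without background correction (-0.99). Of 20 imprinted genes 8 were higher and 1 lower (adjusted p = 0.0382, and adjusted p = 0.0654 with an estimated correlation), among them CDKN1C, a cyclin-dependent kinase inhibitor (11.8-fold higher), MEST (6.41-fold higher) and ZIM2 (-1.79 ± 0.07). ZIM2 stood 1.90 above untreated cells in GFP, and in BRG1 it was 0.27 above DMSO and not called. Of 27 cancer-testis and germline genes 4 were lower and 0 higher (adjusted p = 0.0288, and adjusted p = 0.0654 with an estimated correlation), among them STK31 and PAGE2 (2.86-fold and 2.56-fold lower). Without background correction STK31 (-0.78) and PAGE2 (-0.81) lost their calls. PAGE2 stood 2.54 above untreated cells in GFP and 1.19 above them in BRG1, where it was called higher against DMSO. Counts adjusted over each of these lists alone were the same.

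The remaining lists were not called for BRG1 against GFP. Among the subunits of SWI/SNF, 1 of 27 was higher and 1 lower (adjusted p = 0.538). SMARCA4 entered this list through probe A_23_P39034 and was not called, so the count and test leave out the rise on its other probes. Of 7 inhibitors of cyclin-dependent kinases 1 was higher and 1 lower (CDKN2D, -1.33 ± 0.07, and -0.91 with median centring), and CDKN1A was not called (0.80 ± 0.06; adjusted p of the list 0.612). The probe used for CDKN1A was one of those with CCTCCC, and on a probe without it CDKN1A passed the call (1.32), as it did with median centring (1.24) and in the Cy3 channel alone (1.14). Counts of higher and lower genes were 6 and 1 of 23 p53 targets, 0 and 0 of 22 histone genes, 4 and 0 of 14 genes raised by histone deacetylase inhibitors, and 2 and 0 of 26 chromatin enzymes. They were 3 and 0 of 35 interferon-stimulated genes, 7 and 1 of 23 antigen presentation genes, 6 and 2 of 33 genes often methylated in lung cancer, and 7 and 0 of 19 genes responsive to TGF-beta. They were 1 and 0 of 10 metallothioneins, 3 and 2 of 27 inflammatory genes, 6 and 0 of 26 immediate early genes, 4 and 4 of 26 apoptosis regulators, and 4 and 0 of 18 housekeeping genes. Adjusted p-values of these lists lay between 0.0608 and 0.963. For the methylated list and for the blood, immune and endothelial markers, the mean was positive while the median and the test were negative. With median centring the medians of SWI/SNF subunits (-0.13 to 0.32), histone genes (-0.29 to 0.06) and inflammatory genes (-0.04 to 0.15) changed sign, and in the Cy3 channel alone those of metallothioneins (0.02 to -0.15) and housekeeping genes (0.20 to -0.01).

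Markers of other cell types moved both ways. Of 33 neuronal and neuroendocrine genes, 5 were higher, with L1CAM the highest (3.97-fold), and 4 were lower, among them CHGB (2.76-fold lower), with a list adjusted p of 0.565. L1CAM lost its call without background correction (0.986) and with the mean of all probes (0.999), its other probe differing by 0.01, and CHGB without background correction (-0.87). Of 26 lung lineage markers GATA6 was higher (4.55-fold) and 3 were lower, among them the secretoglobins SCGB1A1 (-2.28 ± 0.07) and SCGB3A2 (-2.10 ± 0.12), both measured by probes with CCTCCC and above untreated cells in GFP (2.56 and 2.16), with a list adjusted p of 0.312. NKX2-1, the lung lineage factor gene, was not called (0.31 ± 0.08). Of 18 blood, immune and endothelial markers 4 were higher and 1 lower (adjusted p = 0.433).

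The control cultures themselves differed. In DMSO against GFP 2028 genes were called, 1123 higher and 905 lower, and these cultures differ in virus, vehicle, culture and slide together. Against DMSO in place of GFP, 1540 genes were called for BRG1. Of the 2679 genes called against GFP, 866 (32.3%) were called in the same direction against DMSO, or 39.5% of the higher and 16.2% of the lower genes, and 9 were called in the opposite direction. Of the named genes, CDC45, CHAF1B, RRM2, CDKN2D, SCGB1A1, SCGB3A2, HK2, ID3, GBP1 and PSAT1 also had no call against DMSO. Of 30 mitosis genes 16 were higher in DMSO than in GFP and 0 lower (adjusted p = 4.38e-07, and 0.0367 with an estimated correlation), among them CCNB1 (2.89-fold), PLK1 (2.85-fold) and AURKA (2.27-fold). PLK1 lost its call with the mean of all probes (0.87) and AURKA in the Cy3 channel alone. Of 40 DNA replication genes 8 were lower in DMSO than in GFP and 0 higher (adjusted p = 1.58e-05, and 0.0129 with an estimated correlation), RRM2 by 2.20-fold, although RRM2 lost its call with median centring (-0.51) and with the mean of all probes (-0.60).

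The comparison of TSA with DMSO asks which genes respond to inhibition of histone deacetylases. PODXL was again the gene with the largest rise (4.56-fold, 2.19 ± 0.07, n = 4, adjusted p = 1.61e-16), followed by KRT18 (4.23-fold), the ubiquitin-like modifier gene UBD (4.17-fold), the transcription factor gene GATA6 (3.52-fold) and KRT4 (3.38-fold). GADD45A, a gene of the DNA damage response, rose 3.34-fold, BAMBI 3.33-fold and PPP1R14C 3.28-fold. APOE, which encodes apolipoprotein E, fell most (-1.76 ± 0.05), followed by COL6A1 (-1.51 ± 0.11), CCDC78 (-1.45 ± 0.08), HAPLN1 (-1.26 ± 0.08), KREMEN2 (-1.22 ± 0.08), FADS2 (-1.20 ± 0.11), GPR162 (-1.17 ± 0.09) and F12 (-1.17 ± 0.07). In all, 57 of 16543 genes were called, 38 higher and 19 lower, and at an adjusted p below 0.05 without the fold minimum 4105 passed. Several of the named calls depended on the processing: without background correction BAMBI (0.94), PPP1R14C (0.83) and GPR162 (-0.77) missed the fold minimum, with the mean of all probes COL6A1 (-0.82), FADS2 (-0.72) and GPR162 (-0.73), and in the Cy3 channel alone F12 (-0.93).

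Genes widely reported as raised by histone deacetylase inhibitors shifted upward with TSA (adjusted p = 0.000152, and 0.0309 with an estimated correlation), although 0 of 14 were called, also adjusted over the list alone. Their median difference was 0.30, with CDKN1A at 0.33 ± 0.06 and TXNIP at 0.45 ± 0.07. Histone genes (0 of 22 called, median 0.22, adjusted p = 0.00246) and DNA replication genes (0 of 40 called, median 0.16, adjusted p = 0.00543, with MCM5 at 0.12 ± 0.08) were shifted upward too. So were interferon-stimulated genes (median 0.05, mean 0.19, adjusted p = 0.00394), where 1 of 35 was called, IFI6 (2.06-fold), and IFIT1 stood at 0.74 ± 0.09. IFI6 lost its call without DMSO array 2 (0.99), without DMSO array 3 (0.98), without TSA array 1 (0.99) and in several normalisations. With median centring the medians were 0.16 for interferon-stimulated genes, 0.15 for genes raised by deacetylase inhibitors, 0.09 for histone genes and 0.04 for DNA replication genes. These 4 lists stayed below 0.05 with an estimated correlation (largest adjusted p = 0.0436), and their counts adjusted over the list alone were the same.

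Among lists not called for TSA, CDH1 rose 2.98-fold and KRT18 4.23-fold of 29 epithelial genes while CLDN3 was lower (-1.03 ± 0.08; list adjusted p = 0.947). CLDN3 lost its call without DMSO array 1 (-0.98), without background correction (-0.92), with the processed signals (-0.94) and with the mean of all probes (-0.63), and CDH1 did so without background correction (0.97). COL3A1 (-1.09 ± 0.05) and COL6A1 were the 2 of 30 mesenchymal genes that were lower (0.362). Of 19 genes responsive to TGF-beta 4 were higher, BAMBI and the transcriptional inhibitor genes ID1 (2.67-fold), ID2 (2.48-fold) and ID3 (2.05-fold), and 1 lower (0.0705). ID3 missed the fold minimum without DMSO array 2 (0.99) or TSA array 1 (0.99). Higher and lower counts were 1 and 0 for the list of genes responsive to BRG1 or BRM (0.0587), p53 targets (0.144), genes often methylated (0.263), neuronal genes (0.262), adhesion genes (0.973) and stress genes (0.827). They were 2 and 0 for lung lineage markers (0.233) and 1 and 1 for immediate early genes (0.517). No member was called among SWI/SNF subunits (0.803), mitosis genes (0.973), kinase inhibitors (0.409), chromatin enzymes (0.891), antigen presentation genes (0.941), cancer-testis genes (0.833), imprinted genes (0.803), blood, immune and endothelial markers (0.858) or cholesterol synthesis genes (0.138). Nor was any among heat shock genes (0.858), metallothioneins (0.0858), inflammatory genes (0.0604), hypoxia genes (0.803), apoptosis regulators (0.262) or housekeeping genes (0.0723). Values in parentheses after list names are camera adjusted p-values. The median, the mean and the test differed in sign for SWI/SNF subunits, mitosis, adhesion, mesenchymal genes and the blood, immune and endothelial markers.

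The comparison of 5dAzaC with DMSO asks which genes respond to inhibition of DNA methylation. Several of the largest rises were in genes of the amino acid stress response. TRIB3, a pseudokinase gene, rose 21.7-fold (4.44 ± 0.09, n = 4, adjusted p = 1.16e-20), ATF3 9.30-fold, the asparagine synthetase gene ASNS 9.18-fold, NIBAN1 8.30-fold, the matrix protein gene EMILIN2 7.34-fold, PSAT1 6.37-fold, the transcription factor gene ATF4 6.15-fold and ID2 5.42-fold. The largest fall was in the collagen gene COL3A1 (9.24-fold lower, -3.21 ± 0.05), followed by FKBP10 (8.53-fold), AGR2 (7.68-fold), APOE (7.63-fold), the laminin gene LAMB2 (7.37-fold), FZD2 (6.64-fold), TMEM35A (5.34-fold) and HMCN1 (5.27-fold). In all, 775 of 16543 genes were called, 356 higher and 419 lower (limma).

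Of 25 genes of the unfolded protein and amino acid stress response 10 were higher and 3 lower with 5dAzaC, also adjusted over the list alone (adjusted p = 0.0179, and adjusted p = 0.0724 with an estimated correlation). The higher members included DDIT3, which encodes CHOP (4.50-fold, 2.17 ± 0.32), although the second 5dAzaC array stood at 0.33 against 2.63 to 2.79 on the others, and DDIT3 was not called in the Cy3 channel alone (1.61). Of 3 members that encode chaperones of the endoplasmic reticulum, chosen after their values were seen, PDIA4 (-2.19 ± 0.10) and HSP90B1 (-1.21 ± 0.09, and -0.91 in the Cy3 channel alone, short of the call) fell, and HSPA5 stood at -0.05 ± 0.11. Of 26 immediate early genes 6 were higher, among them EGR1 (3.59-fold), IER2 (2.92-fold) and DUSP6 (2.65-fold), and 1 lower. That list had an adjusted p of 0.0478 and lost the call with an estimated correlation (adjusted p = 0.0666), with the Agilent processed signals (0.0807), with a replicate block (0.0659) and without 5dAzaC arrays 1 (0.0555), 2 (0.051) and 4 (0.0545), DMSO arrays 1 (0.0571) and 2 (0.0588) and GFP array 4 (0.052).

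Matrix genes fell with 5dAzaC. Of 38 adhesion and matrix remodelling genes 6 were lower and 0 higher (adjusted p = 0.00543, and 0.0324 with an estimated correlation), among them LAMB2, LAMA4 (4.45-fold lower), LAMA5 (4.24-fold lower) and ITGA6 (2.52-fold lower). Of 30 mesenchymal genes 3 were lower and 0 higher (adjusted p = 0.00726, and 0.0324 with an estimated correlation), COL3A1, COL6A1 (3.53-fold) and LUM (2.72-fold). Of 25 cholesterol synthesis genes 5 were lower, among them TM7SF2 (2.66-fold), and HMGCS1 was higher (2.49-fold, but 0.50 on the log2 scale and not called with the mean of all probes; list adjusted p = 0.00271, and adjusted p = 0.0641 with an estimated correlation). Of 30 mitosis genes ASPM, KIF20A and NUSAP1 were lower (2.18-fold, 2.12-fold and 2.01-fold) and 0 higher (adjusted p = 2.02e-06, and 0.0324 with an estimated correlation). Without background correction ASPM (-0.99), KIF20A (-0.73), NUSAP1 (-0.74) and, of the mesenchymal genes, LUM (-0.76) lost their calls, and so did ASPM in the Cy3 channel alone (-0.91). NUSAP1 also lost its call in the authors' table (-0.99) and without 5dAzaC array 1 (-0.996), 3 (-0.98) or 4 (-0.96) or DMSO array 2 (-0.95). Of 18 housekeeping genes RPLP0, GAPDH and RPL13A were lower by 2.26-fold, 2.15-fold and 2.12-fold (adjusted p = 0.0219, and 0.0443 with an estimated correlation). With the Agilent processed signals this list was not called (adjusted p = 0.0794). RPLP0 lost its call without DMSO array 1 (-1.0) and in the Cy3 channel alone (-0.94). RPL13A lost its call without DMSO array 1 (-0.97), without background correction (-0.995), with the processed signals (-0.96) and in the Cy3 channel alone (-0.74). Counts adjusted over each of these lists alone were the same.

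A further 3 lists were called with 5dAzaC at the preset correlation alone. DNA replication genes had a median of 0.23 that changed sign to -0.02 with median centring, with 0 of 40 called (adjusted p = 0.0243, and adjusted p = 0.0785 with an estimated correlation). Antigen presentation genes had a median of -0.14 with 0 of 23 called (adjusted p = 0.0248, and adjusted p = 0.0724 with an estimated correlation). Of the 15 genes responsive to BRG1 or BRM in other lines 1 was lower and 0 higher (adjusted p = 0.0169, and adjusted p = 0.0724 with an estimated correlation).

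Lists often examined after loss of DNA methylation were not called. None of 27 cancer-testis and germline genes was called, also adjusted over the list alone (median 0.06, adjusted p = 0.524). Of 35 interferon-stimulated genes ISG20 (3.20-fold) and HERC5 (2.17-fold) were higher, IFI6 (-1.49 ± 0.12), IFIH1 (-1.31 ± 0.09) and ISG15 (-1.06 ± 0.06) lower, and IFIT1 stood at -0.64 ± 0.09 (adjusted p = 0.963). Without background correction HERC5 (0.41) and IFIH1 (-0.83) lost their calls, as did HOXA9 (0.61) and KIF5C (0.66), given below. On the second 5dAzaC array HERC5 stood at 0.65 against 1.47 to 1.52 on the others. Of 33 genes often methylated in lung cancer HOXA9 was higher (2.34-fold) and CADM1 and SFRP4 were lower (4.49-fold and 2.67-fold) (adjusted p = 0.696). Of 20 imprinted genes 3 were higher and 0 lower (0.2), and of 26 chromatin enzymes none was called (0.592), with DNMT1 at -0.36 ± 0.12. Of 7 kinase inhibitors none was called (0.827), CDKN1A standing at -0.11 ± 0.06. Higher and lower counts were 1 and 1 of 23 p53 targets (0.963), 0 and 2 of 22 histone genes (0.138), 0 and 3 of 14 genes raised by deacetylase inhibitors (0.0723), and 0 and 1 of 29 epithelial genes (0.669). They were 5 and 0 of 19 genes responsive to TGF-beta (0.0939), 1 and 0 of 33 neuronal genes (0.696), KIF5C being 3.41-fold higher, and 1 and 0 of 26 lung lineage markers (0.693). They were 0 and 1 of 18 blood, immune and endothelial markers (0.639), 0 and 2 of 16 heat shock genes (0.694), and 3 and 0 of 27 inflammatory genes (0.066). They were 1 and 2 of 24 hypoxia genes (0.603) and 1 and 1 of 26 apoptosis regulators (0.963), and no metallothionein (0.683) or SWI/SNF subunit (0.833) was called. The median, the mean and the test differed in sign for p53 targets, interferon-stimulated genes, genes often methylated, epithelial genes, lung lineage markers, heat shock genes, metallothioneins, apoptosis regulators and SWI/SNF subunits.

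The series sets BRG1 beside the drugs, and the number of shared genes differed between the pairs. BRG1 and TSA shared 18 higher genes, where independent lists would share 4.26, and 1 lower gene (0.95), while 10 genes higher with BRG1 were lower with TSA, among them APOE, COL6A1, CCDC78 and KREMEN2, and 1 was the reverse. PODXL, KRT18, CDH1, GATA6, GADD45A and BAMBI were higher in both. BRG1 and 5dAzaC shared 42 higher genes (39.9 for independent lists) and 8 lower ones (20.8), while 175 genes higher with BRG1 were lower with 5dAzaC and 40 the reverse. COL3A1 was among those higher with BRG1 and lower with 5dAzaC. For calls in opposite directions no number for independent lists was computed. The shared counts alone therefore do not show that BRG1 and a drug moved genes the same way. TSA and 5dAzaC shared 9 higher genes (0.82) and 12 lower genes (0.48), but both were compared with the same DMSO culture, which independent lists would not be. ATF3, ID3 and PPP1R14C were higher in all 3 comparisons, and GCG, the glucagon gene, was lower in all 3 (-2.03 ± 0.19, -1.16 ± 0.19 and -1.85 ± 0.19). PPP1R14C with 5dAzaC (1.00 ± 0.09) missed the fold minimum without 5dAzaC arrays 1 (0.96), 3 (0.96) or 4 (0.99) or DMSO arrays 2 (0.99) or 3 (0.97), and ID3 with TSA as given above. Without background correction PPP1R14C missed it with BRG1 (0.62), TSA (0.83) and 5dAzaC (0.36), and ATF3 (0.84), GCG (-0.87) and ID3 (0.98) missed it with TSA. So did ATF3 with TSA with the mean of all probes (0.74), ID3 with TSA with median centring (0.84), and in the Cy3 channel alone ID3 with BRG1 (0.95) and PPP1R14C with 5dAzaC (0.92).

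Across genes, which are not independent replicates, the log2 differences correlated at -0.09 (Spearman -0.12) for BRG1 and TSA, at -0.20 (-0.18) for BRG1 and 5dAzaC and at 0.43 (0.40) for TSA and 5dAzaC, the 3 pairs computed. The last pair shares its DMSO arrays. In 50 simulations of unchanged groups sharing those arrays r averaged 0.50, so the correlation alone does not show a shared response. The observed covariance of 0.0454 exceeded the simulated 0.00344. With the DMSO arrays parted between the drugs the shared genes numbered 18 to 24 and r was 0.31 to 0.42. The simulations held no departure of the DMSO culture itself, and the parted arrays come from that same culture and slide. So neither check can tell a response shared by the drugs from such a departure, which both comparisons subtract. Against untreated cells 3 genes were called in DMSO, so a called departure of that culture can underlie at most 3 of the shared genes. Smaller departures stay open. Ratios to untreated cells, which do not use the DMSO arrays, correlated across genes at 0.393 for TSA and 5dAzaC. They correlated at 0.515 for TSA and DMSO and at 0.13 for 5dAzaC and DMSO, but all share the untreated reference.

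Tests of the differences themselves called 3108 genes between the BRG1 and TSA effects, 4000 between the BRG1 and 5dAzaC effects and 544 between TSA and 5dAzaC. GPNMB (5.44 ± 0.15), ADGRG1 (5.42 ± 0.13) and HAS1 (5.09 ± 0.13) were among the genes that differed most between BRG1 and TSA. ADGRG1 (6.49 ± 0.13), COLEC12 (6.17 ± 0.29), GPNMB (5.98 ± 0.15) and IFI30 (5.88 ± 0.14) differed most between BRG1 and 5dAzaC. TRIB3 (-4.60 ± 0.09), ASNS (-2.98 ± 0.08), COLEC12 (2.68 ± 0.20) and ATF4 (-2.68 ± 0.10) differed most between TSA and 5dAzaC. For COLEC12 the second 5dAzaC array stood at -1.08 against -2.58 to -2.47 on the others.

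These tests measure array error, since each treatment had 1 culture on 1 slide. With arrays averaged to 1 value per treatment and GFP and DMSO taken as a pair of controls, limma called 0 genes for BRG1, TSA and 5dAzaC, and at an unadjusted p below 0.05 with the 2-fold minimum 990, 37 and 404. That fit had 1 residual degree of freedom and treated as replicates 2 cultures that differed in 2028 called genes, so its count of 0 does not show that the treatments had no effect.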

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

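Of the tests in this part, the share of lower calls that lay in the GFP culture and the count in the reference channel were chosen after the result was seen. Single arrays were compared with the other 3 of their group by Dixon's test, and 31 of 503 groups held an array far from the others, where chance gives about 1 in 20, or 25.1. The named genes make up 323 of these groups.

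The second 5dAzaC array was dim, with 29291 probes well above background against 34697 to 35431 on the others and an SD of log2 ratios of 0.403 against 0.471 to 0.481. On it DDIT3 stood at 0.326 (2.63 to 2.79 on the others), HERC5 at 0.651 (1.47 to 1.52), COLEC12 at -1.081 (-2.58 to -2.47) and the median of kinase inhibitor genes at 0.087 (-0.02 to -0.01). On the third 5dAzaC array HMGCS1 stood at 1.842, ISG20 at 1.584 and the median of lung lineage markers at -0.036. The fourth BRG1 array had a median net Cy3 signal of 280.2 (363.4 to 371.6 on the others). On that array LAMB1 stood at 2.763, SCGB3A2 at 0.308 and PSAT1 at -0.622 (-0.94 to -0.91 on the others).

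Elsewhere in BRG1, EPCAM stood at 1.265 and NUF2 at -1.499 on the first array, VLDLR at 3.006 on the second and MEST at 3.47 on the third. In GFP the first array stood out for SERPINH1 (0.477) and antigen presentation genes (0.077), the second for PDGFRB (-0.855), the third for MEST (0.781), histone genes (0.208) and cholesterol genes (-0.133), and the fourth for CCNB1 (-1.937) and the SMARCA4 probe A_23_P39034 (-1.042). In DMSO the first array stood out for apoptosis regulators (0.088), the second for NUSAP1 (0.149), and the fourth for PODXL (0.282) and UBD (0.061). In TSA it was the first array for heat shock genes (-0.047) and the fourth for the SMARCA4 probe A_23_P39040 (0.528). No explanation was tested for these single values.

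The treatments differed from each other by tests of the difference itself, with 3108 genes for the BRG1 and TSA effects, 4000 for the BRG1 and 5dAzaC effects and 544 for TSA and 5dAzaC. DNA replication genes were lower with BRG1 relative to TSA (median difference -0.887) and relative to 5dAzaC (-0.92). These differences use the GFP control, where the list median stood 0.62 above untreated cells. It was -0.09 in BRG1, 0.04 in DMSO, 0.23 in TSA and 0.27 in 5dAzaC. Against DMSO the median difference of BRG1 was 0, so much of the size came from the GFP culture. Relative to 5dAzaC, BRG1 was higher in genes responsive to BRG1 or BRM in other lines (1.556), adhesion genes (1.243), cholesterol genes (1.096) and mesenchymal genes (0.65). Among the 11615 probes with no gene name, which the comparisons left aside, 1212 were called for BRG1 against GFP (495 higher and 717 lower, 78 of the lower holding CCTCCC), 52 for TSA (44 higher and 8 lower) and 314 for 5dAzaC (168 higher and 146 lower).

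Most genes called in BRG1 against GFP were not called in BRG1 against DMSO. A difference between slides that moved the reference channel, alone or unequally with the treated one, is argued against, since the reference channel gave 12 calls. Equal changes in both dyes cancel in the ratio, and a slide difference in the treated channel alone was not tested and stays open. For the lower genes the departure lay mostly in the GFP culture, 69.6% of them standing further from untreated cells in GFP than in BRG1 (573 of 823), so a candidate explanation for many of them is a change in the GFP culture or its slide. For the higher genes the share was 33.8% (627 of 1856), which decides nothing. Both shares were taken over all calls, and 733 of the higher and 133 of the lower genes were also called against DMSO. Those genes are not part of the pattern, and the shares without them were not computed. In either direction virus, culture and slide cannot be told apart with 1 culture per treatment. A response to the virus itself that BRG1 lessens stays open and was not tested.

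Among the called stress genes more were higher than lower in 5dAzaC against DMSO, and matrix genes were lower. The stress list was called at the preset correlation and not with an estimated one. For the stress genes a slide difference that moved the reference channel, alone or unequally with the treated one, is argued against, since the Cy5 change of the 10 higher ones was -0.027 of their change in the log2 ratio (medians -0.07 and 2.40). One in the treated channel alone was not tested and stays open. The dim array does not account for it either, since 100% of the 22 called members of the stress, adhesion and mesenchymal lists stayed called without that array. The vehicle or handling of the 5dAzaC culture and the drug cannot be told apart for the 775 called genes, since each treatment had 1 culture and the labels do not name the vehicle. The drug therefore stays a hypothesis.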

How the results depend on the processing

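Leaving out the CCTCCC probes and counting genes called against both controls were chosen after seeing the data. Counts are given in the order BRG1 against GFP, TSA against DMSO, 5dAzaC against DMSO, DMSO against GFP, BRG1 against TSA effects, BRG1 against 5dAzaC effects, and TSA against 5dAzaC, where the main counts were 2679, 57, 775, 2028, 3108, 4000 and 544. Without background correction the counts were 1400, 25, 387, 803, 1735, 2402 and 300, and the cause was not tested. Without a fold minimum they were 12516, 4105, 8441, 12055, 11380, 12141 and 7891, at 1.5-fold 6079, 461, 2843, 5407, 6554, 7516 and 2270, and at 3-fold 773, 9, 123, 382, 1003, 1603 and 95, as those limits let more or fewer genes through. With every probe tested separately they were 4838, 123, 1318, 3819, 5744, 7530 and 1006, since more features were tested.

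With the Agilent processed signals the count was 127 for TSA, 1258 for 5dAzaC, 3431 for DMSO against GFP and 921 for TSA against 5dAzaC, and the cause was not tested. Median centring gave 3874 for DMSO against GFP and moved the median of all genes by 0.22 there, by 0.21 in BRG1 against GFP, by 0.24 between the BRG1 and TSA effects and by 0.31 between the BRG1 and 5dAzaC effects. The share of called genes that were higher then went from 69.3% to 90.1% for BRG1, from 45.9% to 18.8% for 5dAzaC and from 55.4% to 84.7% for DMSO against GFP. For 5dAzaC more genes were higher than lower at 1.5-fold (1518 and 1325), without a fold minimum (4653 and 3788), against both controls together (583 and 351) and against the untreated reference (415 and 293). For TSA more were lower at 1.5-fold (249, and 212 higher). So the balance of higher and lower genes depends on the scaling, the fold minimum and the control. With arrays averaged and GFP and DMSO as a pair of controls, limma called 0 genes in BRG1, TSA, 5dAzaC and the 3 differences between treatments, with 1 residual degree of freedom and controls that differed in 2028 called genes, and 990, 37 and 404 passed an unadjusted p below 0.05 and 2-fold for the first 3. DMSO against GFP could not be fitted that way.

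The control mattered. BRG1 gave 1540 genes against DMSO, 1454 against both controls together, 1773 against the untreated reference and 866 called against both GFP and DMSO. TSA gave 1937 against GFP and 243 against both together, and 5dAzaC 2461 against GFP, where the drug and the adenovirus differ together. The overlap of 82 genes called alike in at least 2 comparisons (19 for BRG1 and TSA, 50 for BRG1 and 5dAzaC, 21 for TSA and 5dAzaC) was 687 (125, 396 and 252) at 1.5-fold and 10 (5, 4 and 1) at 3-fold. With TSA and 5dAzaC against GFP and BRG1 against DMSO it was 1390, with 66 for BRG1 and TSA and 1293 for TSA and 5dAzaC, which then share the GFP arrays. Of 90 list tests 26 were called, 16 with an estimated correlation and 73 with fry, which tests each list on its own.

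Leaving out 1 array at a time gave 2658 to 2726, 54 to 63, 731 to 893, 1987 to 2079, 3070 to 3150, 3961 to 4083 and 521 to 638 genes in the same order. The overlap ranged over 78 to 98 (18 to 24, 47 to 68 and 19 to 23 per pair) and the list tests over 25 to 29. The other alternatives kept these counts within 1.5-fold. Among them, the authors' table gave 2689, 57 and 778 genes for BRG1, TSA and 5dAzaC, sharing 2628, 56 and 751 with the main analysis. Requiring signal well above background on all 20 arrays gave 2472, 56 and 759, but probes that pass this can still be dim, and how far low signal bears on the calls was not tested. With the replicate number as a block the counts were 2680, 57 and 775, and of the named genes and lists the immediate early list in 5dAzaC alone was not called (adjusted p = 0.0659). Arrays of the same number also share their position on the slide, and the labels name no other tie between them. Their residuals correlated at 0.083 to 0.567 in 5dAzaC against DMSO, where 4 of 4 correlated best with their own number, at -0.017 to 0.235 in BRG1 against GFP (3 of 4) and at -0.082 to 0.48 in TSA against DMSO (2 of 4). A block for slide or scan date could not be fitted, since each slide holds 1 treatment. For genes named in the text, 2856 of the values under alternatives kept their side of the threshold, 79 fell below it and 7 rose above it, and for lists 2341 did, 23 and 66. None reversed among these, where a list counted as reversed only if it was called both times. Many of these values came from leaving out single arrays. The list tests were not repeated with median centring, without background correction or with the mean of all probes. Of the called lists, mitosis in BRG1 against GFP (-0.14 to 0.25) and DNA replication in 5dAzaC (0.23 to -0.02) had medians that changed sign with median centring.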

Other observations

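The search for a sequence in the probes, the comparison with other probes of the same genes and the repeat in probes left aside were chosen after the result was seen.

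Both adenovirus cultures had mitosis genes below untreated cells and DMSO did not, so 19 of 30 were lower in BRG1 against DMSO and 2 against GFP. BIRC5 was an exception, lower in BRG1 against both GFP (-1.72) and DMSO (-1.51) and near untreated cells in GFP (0.11). CDKN1A stood 1.29 above untreated cells in GFP and 2.09 in BRG1, and was called against DMSO (2.08). Its probe holds CCTCCC, and another probe without it stood at 0.82 in GFP and 2.13 in BRG1. HSPA6 was among the 12 of 16 heat shock genes higher in BRG1 against DMSO. In 5dAzaC the rise of ATF4, TRIB3, ASNS and PSAT1 came with falls in PDIA4 and HSP90B1, while in BRG1 ASNS and PSAT1 fell and ATF3 rose.

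Probes holding CCTCCC were higher on the GFP arrays. In a search of 4096 sequences in 18151 probes, 53 of 174 probes chosen as raised in GFP and not in BRG1 held it, where 2.7 would be expected. The 515 detected probes with it had a median log2 ratio of 0.93 in GFP and 0.05 in BRG1, and 23.7% stood at 1.5 or more against 0.89% of the others. Of the genes called in BRG1 against GFP, 118 of the 823 lower and 13 of the 1856 higher rested on such probes.

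For this pattern a signal of the slide that reached both dyes unequally is argued against, since the Cy5 shift was 0.017 of the Cy3 shift (an equal one would cancel in the ratio), and so is a change in the transcripts, since other probes of 168 such genes had 0.058 of the shift (0.05 against 0.85). The 18152 probes left aside were not new data, since the pattern had been seen before the search. Among them the 234 with CCTCCC stood 0.939 above the rest, and those with the reverse complement 0.03. A candidate explanation is hybridisation of labelled RNA of the GFP culture to that sequence. A slide signal in the treated channel alone was not tested and stays open.

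Other probes of called genes gave a further view. Where another probe existed, it moved by at least 0.5 in the same direction for 62% of the higher and 33.3% of the lower genes in BRG1 against GFP, for 7 of 12 and 1 of 7 in TSA, and for 35.4% and 59.6% in 5dAzaC.

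The arrays were also regrouped, but this cannot exclude chance for the gene counts and says nothing on cultures. Mixed splits place the differences between cultures inside the groups, so their counts are no measure of what chance gives. For BRG1 against GFP, TSA against DMSO and DMSO against GFP, 1 of 35 splits, the real one, gave as many genes (2679, 57 and 2028, and 0 at most otherwise). The same was so for 5dAzaC (775 against 42) and for TSA against 5dAzaC (544 against 15). Of 100 splits each, 1 gave as many for the BRG1 and TSA effects (3108 against 1981), the BRG1 and 5dAzaC effects (4000 against 3031) and the overlap (82 against 0). For the number of list tests called chance was not excluded either, and 14 of 100 splits gave as many (26 against 36).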
